A study of Ictidomys tridecemlineatus with 10 samples.

How the data were processed

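Total RNA was extracted with TRIzol from ground squirrel retinas, in 6 hibernating and 4 awake samples. Libraries were made with a stranded TruSeq total RNA kit, per the labels' protocols. TopHat2 2.0.11, a spliced read aligner, and bcl2fastq, which converts sequencer output to reads, are named per the submitters' processing notes. The genome build, the annotation release, the read counter and its strand setting are not given in the sources used here. The deposited table holds whole-number counts per Ensembl gene identifier.

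Samples were grouped by their labels before the data were examined, and the tests and 54 gene lists were fixed at the same time. The planned test of hibernating against awake retinas was a quasi-likelihood test on the counts. It was not run, because no column could be tied to a sample. Each column name, and the name the accompanying note gives it, was compared with the title and description of every sample, with case, spaces and punctuation ignored. A second comparison searched every label of each sample for the name as a separate word. The 10 columns that matched no sample were not used, beyond a look at their values and totals to establish that they hold counts. Assigning them by column order or by accession order was ruled out, since a wrong order could put samples in the wrong group.

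Row identifiers were matched against a RefSeq gene table of the species (assembly mIctTri1.hap1), first through its Ensembl column and then through all of its name and accession columns, with version suffixes removed. Matching was done in Python 3.11.15. No coordinates from that assembly were used.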

Results

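Retinal RNA from the ground squirrel Ictidomys tridecemlineatus, a hibernating rodent whose retina is dominated by cone photoreceptors, was profiled by RNA sequencing. The labels describe 10 samples in 2 groups. The hibernating group holds 6 retinal samples taken in winter, and the awake group holds 4 taken in summer. The design implies a single comparison, which asks how the retinal transcriptome differs between hibernation and the active season. Season and hibernation state coincide in this design, so a difference between the groups could not be assigned to either of them alone.

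The expression values were deposited as a single table with a row for each of 19440 Ensembl gene identifiers and 10 columns of counts. The column names are a letter and a running number, and an accompanying note pairs each of the 10 with an equally generic sample name. None of these names occurs in the title or description of a sample, so 0 of the 10 columns could be assigned to a hibernating or an awake retina by name. The order of the columns and the order of the samples were not used to assign them. No expression value, depth or difference between hibernating and awake retinas is therefore reported here.

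The row identifiers could not be linked to gene symbols with the reference gene table used. All 19440 row identifiers were ground squirrel Ensembl genes, and the table carried no symbols. The reference gene table of the same species listed 42748 genes, of which 0 had an Ensembl identifier, and 0 of the 19440 identifiers could be paired with a symbol. The 54 gene lists fixed for the comparison were not tested, because their test needed both gene symbols and columns assigned to groups. They covered cone and rod phototransduction, markers of the retinal cell classes, fatty acid oxidation, the circadian clock and chaperones, among other groups.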

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

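The matching rules compared here were chosen after seeing the data. A search of every label for the column name as a word, a comparison of the note's names with titles and descriptions, and a search of every label for the note's names each matched 0 of the 10 columns. A search of all name and accession columns of the reference table also paired 0 of the 19440 gene identifiers with a symbol. This is no independent check, because 0 genes in that table had an Ensembl identifier. Both searches describe the reference table and not the deposited identifiers. The tests planned for the comparison were not run, because they need columns assigned to groups. No paired analysis was possible because no column was assigned to a sample. The labels number the samples within each group, and nothing in them ties a hibernating sample to the awake sample with the same number.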
